A study of Mus musculus with 15 samples.

How the data were processed

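Gene expression was measured on Affymetrix mouse arrays in primary neural stem cell cultures. The 15 arrays fell into 4 groups read from the sample titles, because the treatment label of the treated samples names only the cells: control total RNA (n = 4), CD95L-T4 total RNA (n = 4), control polysomal RNA (n = 4) and CD95L-T4 polysomal RNA (n = 3). Replicates are called biological in the titles. Per the labels, total RNA was extracted with a column kit and polysomal RNA with phenol and chloroform, and the molecule is given as total RNA for the former and polyA RNA for the latter. RNA fraction, extraction method and this molecule label therefore cannot be separated. No processing date or batch is given.

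The deposited table holds log2 values that the authors normalised between arrays, rounded to 2 decimals; the method is not stated. The highest tested value of an array was 14.37 to 14.47 and quantiles were nearly equal in every array, as for log2 of scanner intensities. All columns belonged to mapped samples. Of the 22690 probe sets, the 64 Affymetrix control probe sets were left out of the tests and 22626 were tested. Of these, 20380 had 1 gene, 691 had several and 1555 had none. The reference gene table (assembly GRCm38.p6) was used for current names only, and 12369 of the 12393 genes were found in it by gene identifier. A gene with several probe sets was represented by the one with the highest mean over all arrays. Array data carry no read depth, so the number of arrays limits the precision.

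The log2 values were fitted in limma 3.58.1 under R 4.3.3 with 1 mean per group over all 15 arrays and empirical Bayes moderation (5.78 prior degrees of freedom). The contrasts, each two-sided, were CD95L-T4 against control in total RNA, the same in polysomal RNA, the difference between these effects (the interaction), and polysomal against total RNA in control and in CD95L-T4 cultures. P-values were adjusted by Benjamini and Hochberg over the 22626 probe sets of a contrast, with a threshold of 0.05. Errors of fold changes are limma's moderated standard errors.

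Gene lists were tested with camera, which compares a list with all other genes, at its preset correlation of 0.01, and adjusted over the 29 lists within a contrast. The lists held death receptor and apoptosis genes, the PI3K Akt mTOR pathway, ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, ATF4 and amino acid response, ER chaperones and unfolded protein response, secreted and membrane proteins made at the endoplasmic reticulum (ER), extracellular matrix and adhesion, mitosis, DNA replication, p53 targets, interferon response, NF-kB response, immediate early genes, cholesterol biosynthesis, glycolysis and hypoxia, oxidative phosphorylation, Notch and Wnt targets, noncoding RNAs, histones, and markers of neural stem cells, neurons, oligodendrocyte lineage, astrocytes, microglia, endothelium, fibroblasts and ependyma. Each call was repeated with a correlation estimated from the data and with fry, which asks only whether a list moves one way. In 20 sets of permuted residuals without any effect, camera with the preset correlation called at least 1 list in 15, 15, 17, 11 and 17 sets for the contrasts in the order given above. With an estimated correlation it did so in 1, 0, 0, 0 and 0 sets.

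Groups, contrasts, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, per contrast, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap. Where fewer than 10 genes passed, it took the 10 with the smallest p. It added members of each called list in order of p and 16 genes of CD95 signalling and cell identity, of which 15 were measured. The rule left the number of members per list between 2 and 4, and 3 was settled on only after values had been seen. In the CD95L-T4 fraction contrast the 15 genes are given as values but were not put through the alternatives.

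The steps were tested on simulated data with 200 changed probe sets among 22626 in 20 draws. Noise was drawn independently for each probe set and array, so the rates below do not cover structure shared by the probe sets of an array. Of 1.5-fold changes, 79.9% were recovered in the total RNA contrast, 74.2% in the polysomal contrast and 44.5% in the interaction. Of 2-fold changes, 98.4%, 97.6% and 88.3% were recovered. In the fraction contrasts 81.7% (control) and 75.6% (CD95L-T4) of 1.5-fold changes were recovered, and false calls made up 4.5% to 5.2% of calls over all 5 contrasts.

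Alternatives were other scalings between arrays (quantile over all arrays or within a fraction, equal medians), leaving out the dimmest 25% or 50% of probe sets, fitting the compared groups alone, a trended and robust variance, array weights, a replicate block, a size threshold of 0.5 in log2, the mean of all probe sets of a gene, and leaving out each array in turn. A pseudocount was not tried, since the table is already in log2. Further alternatives were added after the data were seen: the level of the poly-A controls as a covariate, polysomal arrays scaled to equal distance from total RNA, and leaving out the array with the highest poly-A controls of each fraction. These controls, the mean of 12 probe sets, detect bacterial transcripts that are added before labelling, so that a higher value can follow from less sample mRNA. Figures were drawn with matplotlib 3.10.9.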

Results

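Neural stem cells of female mice aged 6 weeks were cultured as neurospheres, free-floating cell clusters, with or without CD95L-T4, a trimerised form of the ligand of the death receptor CD95 (Fas). After 48 h, RNA was prepared from whole cells (total RNA) or from polysomes, which hold mRNA bound by several ribosomes (polysomal RNA). The 4 groups were control total (n = 4 arrays), CD95L-T4 total (n = 4), control polysomal (n = 4) and CD95L-T4 polysomal (n = 3). Array medians lay between 6.83 and 6.98 in log2. Arrays of a group correlated at 0.994 to 0.998, and arrays of different fractions at 0.968 to 0.978. The first principal component held 79.7% of the variance and parted the fractions, whereas the second held 4.05%. Added poly-A control transcripts averaged 7.98 ± 0.29 (SD, n = 4) in control total, 8.002 ± 0.51 (n = 4) in CD95L-T4 total and 8.87 ± 0.28 (n = 4) in control polysomal arrays. In the CD95L-T4 polysomal arrays they averaged 8.92 ± 0.94 (n = 3), with 10.01 in replicate 2 against 8.31 and 8.45 in the others. The 3' minus 5' difference of beta-actin, a measure of RNA integrity and labelling, was 0.41 ± 0.12 (n = 4) in control total and 0.77 ± 0.03 (n = 4) in control polysomal arrays. It was 0.39 ± 0.07 (n = 4) in CD95L-T4 total and 0.77 ± 0.23 (n = 3) in CD95L-T4 polysomal arrays, with 0.59, 0.68 and 1.03 in polysomal replicates 1, 2 and 3.

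The first question was which mRNAs changed in level after CD95L-T4. In total RNA no gene passed the test. The smallest p belonged to Tgfb1, which encodes the cytokine transforming growth factor beta 1, at a log2 fold change of 0.43 ± 0.08 (SE, n = 4 and 4, adjusted p = 0.669). Fas, the receptor of the ligand, stood at 0.00 ± 0.12 and was dim in all groups, at the 23.7th percentile of probe sets. Casp8, the initiator caspase of the receptor, stood at 0.14 ± 0.09, and the kinases Akt1 and Mtor at 0.02 ± 0.10 and 0.01 ± 0.10. The stem cell genes Sox2 and Nes stood at -0.18 ± 0.12 and 0.01 ± 0.14, and the proliferation marker Mki67 at 0.03 ± 0.11. The lineage genes Olig2, Gfap, Dcx and Tubb3, of oligodendrocyte progenitors, astrocytes and neurons, lay between -0.03 and 0.12. Further genes with small p were Atoh1 (0.44), Rab40b (0.57), Sema5b (0.40), Cd52 (0.39), Mchr1 (0.37), Tpsg1 (0.34), Lce1g (0.30), Chrdl2 (-0.28) and Ell2 (-0.40), each at an adjusted p of 0.997.

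limma called 0 of 22626 probe sets in total RNA, with 846 (3.74%) at an unadjusted p under 0.05. The 95% confidence interval lay within a 1.5-fold change for 98.2% of probe sets. Without CD95L-T4 total replicate 1 the count at an unadjusted p under 0.05 was 1688 and without CD95L-T4 total replicate 4 it was 550, with 0 called. Of the 29 lists, camera called 4, with small medians. Oxidative phosphorylation genes had a median of -0.04 (adjusted p = 0.000355; adjusted p = 0.606 with an estimated correlation), lower in 3 of 4 arrays, with the complex I genes Ndufb6 at -0.25, Ndufs5 at -0.18 and Ndufs7 at -0.17. That call was lost with quantile normalization over all arrays or within each fraction, where the median was as small as -0.0145. Genes of secreted and membrane proteins had a median of -0.07 (adjusted p = 0.000355; adjusted p = 0.519 with an estimated correlation), lower in 4 of 4 arrays, with the growth factor precursor Grn at -0.27, Igfbp5 at -0.17 and the secretogranin Scg2 at 0.19. The p53 targets had a median of -0.02 (adjusted p = 0.00629; adjusted p = 0.474 with an estimated correlation), lower in 4 of 4 arrays, with the cell cycle inhibitor Gadd45a at -0.28 ± 0.09 the pro-apoptotic Bbc3 at -0.24 ± 0.09 and Perp at -0.22 ± 0.08. Cholesterol biosynthesis genes had a median of 0.06 (adjusted p = 0.0362; adjusted p = 0.519 with an estimated correlation), higher in 4 of 4 arrays, with Nsdhl at 0.15, the regulator Srebf2 at 0.15 and Hsd17b7 at 0.20. The cholesterol call was lost without CD95L-T4 total replicate 1 or 2 or control total replicate 1 or 4, and with the mean of all probe sets of a gene. fry called 0 lists, and 0 members of any list passed, adjusted over all probe sets or adjusted over the list alone. Median, mean and test differed in sign for the PI3K Akt mTOR, ATF4, immediate early, glycolysis and extracellular matrix lists, of which 0 were called.

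The second question was which mRNAs changed in their amount on polysomes. With all arrays, no gene passed in polysomal RNA either. The smallest p belonged to the uncharacterised Gm4802, at -0.57 ± 0.09 (SE, n = 3 and 4, adjusted p = 0.234). Eif4ebp1, a repressor of cap-dependent translation that mTOR inactivates, stood at -0.28 ± 0.10 (adjusted p = 0.474). Col5a2, a fibrillar collagen, stood at 0.48 ± 0.10 and the matrix genes Lamb1 and Tnc at 0.42 ± 0.13 and 0.37 ± 0.13. Pcna, the replication clamp, stood at 0.30 ± 0.12, and Fdps of the cholesterol pathway at 0.39 ± 0.12. Selenop, a secreted selenium carrier, stood at -0.35 ± 0.08 and the histone genes H1f4 and H3c4 at -0.57 ± 0.19 and -0.49 ± 0.17. Fas stood at -0.07 ± 0.13, Casp8 at -0.06 ± 0.10, Mtor at 0.09 ± 0.11 and Sox2 at 0.13 ± 0.13. Other genes with small p included Mylk (0.40), Plek (0.45), Gm5617 (-0.48), Rsph6a (-0.40), ccdc198 (-0.63) and 2310010J17Rik (-0.51), each at an adjusted p of 0.431.

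limma called 0 of 22626 probe sets in polysomal RNA with all arrays, with 2184 (9.65%) at an unadjusted p under 0.05 and a lowest adjusted p of 0.234. The interval lay within a 1.5-fold change for 95.9% of probe sets. The count rested on CD95L-T4 polysomal replicate 2, the array with the highest poly-A controls. Without it, 1386 probe sets passed, 717 higher and 669 lower, of 790 genes, and 4906 had an unadjusted p under 0.05. The 3' minus 5' difference of beta-actin was 0.59 in replicate 1 and 1.03 in replicate 3, the arrays kept. It was 0.68 in replicate 2 and 0.74 to 0.81 in control polysomal arrays. Across genes the effect in replicates 1 and 3 ran against the difference between fractions, with a correlation of -0.462 to -0.252 when the 2 were computed from separate control polysomal arrays. Of the 382 genes called higher, 301 were lower and 81 higher in polysomal than in total RNA of control cultures. Of the 408 called lower, 378 were higher there and 29 lower. Both effects behind these counts share the control polysomal arrays, which by itself favours opposite signs. Among the called genes, Pcna stood at 0.49 (adjusted p = 0.00925), Tnc at 0.58 (adjusted p = 0.00925) and Gsk3b, a kinase downstream of Akt, at 0.69 (adjusted p = 0.0224). Eif4ebp1 then stood at -0.36 (adjusted p = 0.0451), and Ndufa6 of respiratory complex I at -0.40 (adjusted p = 0.0133). These genes too ran against the difference between fractions in control cultures, which was -0.75 for Pcna, -2.93 for Tnc, -0.17 for Gsk3b and 1.28 for Ndufa6. That setting compares 2 CD95L-T4 arrays with 4 controls. A fit to the polysomal arrays alone without replicate 2 called 0, with 4163 at an unadjusted p under 0.05, and 1163 with the poly-A controls as a covariate. Without CD95L-T4 polysomal replicate 1 the count at an unadjusted p under 0.05 was 1351, with 0 called.

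**Figure D1:**
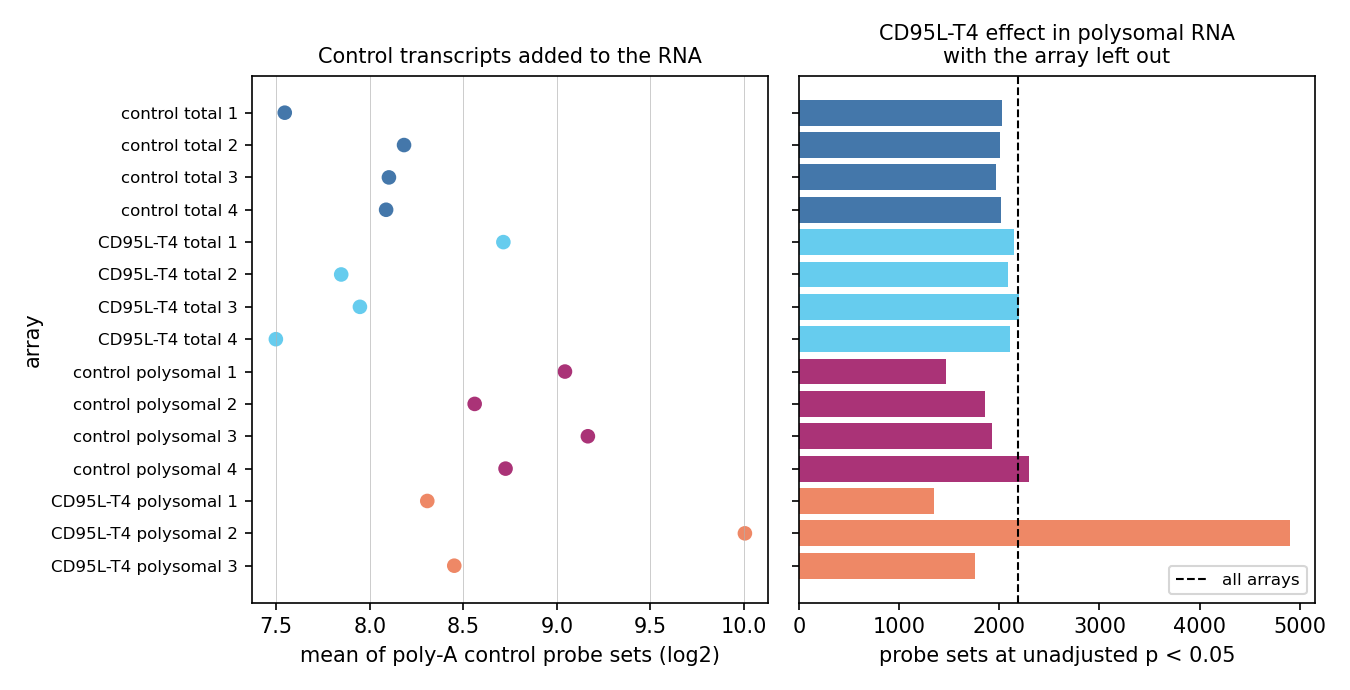
Left, mean log2 value of the 12 poly-A control probe sets of each of the 15 arrays; right, number of probe sets at an unadjusted p under 0.05 for CD95L-T4 against control in polysomal RNA with that array left out, the dashed line marking 2184 with all arrays. CD95L-T4 polysomal 2 has the highest control level, 10.01, and without it the count is 4906.

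Of the 29 lists, camera called 7 in polysomal RNA, none of them with an estimated correlation, where the lowest adjusted p was 0.438, and fry called 0. Oxidative phosphorylation genes had a median of -0.09 (adjusted p = 1.43e-05; adjusted p = 0.438 with an estimated correlation), lower in 3 of 3 arrays, and histones -0.16 (adjusted p = 0.0251; adjusted p = 0.438 with an estimated correlation), lower in 3 of 3 arrays. Translation factors had a median of 0.09 (adjusted p = 0.000242; adjusted p = 0.438 with an estimated correlation), higher in 2 of 3 arrays, with the initiation factor genes Eif3i at 0.22 ± 0.08, Eif2b1 at 0.21 and Eif3c at 0.14. Cholesterol biosynthesis had a median of 0.11 (adjusted p = 0.00714; adjusted p = 0.438 with an estimated correlation), higher in 3 of 3 arrays, but the call was lost without CD95L-T4 polysomal replicate 1, without replicate 2 (adjusted p = 0.08) or without control polysomal replicate 4, and also with a replicate block over all arrays or within each fraction. Extracellular matrix and adhesion genes had a median of 0.09 (adjusted p = 0.00714; adjusted p = 0.438 with an estimated correlation), higher in 3 of 3 arrays, but -0.02 once the polysomal arrays were scaled to equal distance from total RNA. DNA replication genes had a median of 0.06 (adjusted p = 0.0302; adjusted p = 0.499 with an estimated correlation), and PI3K Akt mTOR genes 0.09 (adjusted p = 0.0442; adjusted p = 0.499 with an estimated correlation), each higher in 2 of 3 arrays. Further members with small p were Uqcr10 (-0.29), Ndufa6 (-0.27) and Ndufa4 (-0.22) of oxidative phosphorylation, H2az1 (-0.16) of the histones, Fn1 (0.26) of the matrix, Idi1 (0.23) and Nsdhl (0.20) of the cholesterol pathway, Cdc45 (0.21) and E2f1 (-0.21) of DNA replication, and Gsk3b (0.39) and Pdpk1 (0.19) of the PI3K pathway. The calls of translation factors, extracellular matrix and histones were lost without CD95L-T4 polysomal replicate 1, and that of extracellular matrix also without control polysomal replicate 3. Without CD95L-T4 polysomal replicate 2 most medians were larger: 0.16 for translation factors, 0.14 for PI3K genes, -0.24 for histones and -0.14 for oxidative phosphorylation. They were then 0.13 for extracellular matrix, 0.09 for DNA replication and 0.11 for cholesterol genes. The DNA replication call was lost with a replicate block over all arrays, and without CD95L-T4 polysomal replicate 1 or control polysomal replicate 2, and the PI3K call without CD95L-T4 polysomal replicate 3 or control polysomal replicate 1 or 2. Scaling to equal separation ended the calls of cholesterol, extracellular matrix, histone, DNA replication and PI3K genes, and quantile normalization or leaving out the dimmest 50% of probe sets ended those of histone, DNA replication and PI3K genes. The PI3K call also ended without the dimmest 25% of probe sets and with the mean of all probe sets of a gene. Adjusted over the list alone, 2 histone genes, 2 genes of the ATF4 response, 1 astrocyte gene, 1 ribosomal protein gene and 2 stem cell markers were lower, and 1 stem cell marker and 1 gene of a secreted or membrane protein were higher, whereas over all probe sets 0 passed. Median, mean and test differed in sign for the ependymal, NF-kB and Notch and Wnt lists, of which 0 were called.

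The third question was whether the effect of CD95L-T4 differed between polysomal and total RNA. No gene passed. The smallest p belonged to Nrros, a membrane protein gene, at -0.56 ± 0.12 (SE, n = 3 and 4 polysomal, 4 and 4 total, adjusted p = 0.897). Tgfb1 stood at -0.45 ± 0.11, the ribosomal protein gene Rpl12 at -0.64 ± 0.17 and Igf1r, the receptor of insulin-like growth factor 1, at 0.58 ± 0.17. Ddit4, an inhibitor of mTOR complex 1, stood at 1.43 ± 0.56, with a wide error. Other genes with small p included 2310010J17Rik (-0.71), Slc47a1 (-0.55), Cd52 (-0.57), Lfng (-0.38), Alk (0.44) and Bspry (0.45), each at an adjusted p of 0.897. Fas stood at -0.07 ± 0.17, Eif4ebp1 at -0.19 ± 0.13, Atf4 at -0.14 ± 0.10 and Sox2 at 0.31 ± 0.18.

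limma called 0 of 22626 probe sets in the interaction, with 992 (4.38%) at an unadjusted p under 0.05. The interval lay within a 1.5-fold change for 84.2% of probe sets and within 2-fold for 99.1%. Without CD95L-T4 polysomal replicate 2, 2 probe sets passed and 3540 had an unadjusted p under 0.05. Without CD95L-T4 total replicate 1 the count at an unadjusted p under 0.05 was 1495, with 0 called. camera called 5 lists with the preset correlation, and fry 0. Median differences were 0.09 for genes of secreted and membrane proteins (adjusted p = 0.00104), 0.09 for extracellular matrix (adjusted p = 0.00793), 0.07 for translation factors (adjusted p = 0.00793), 0.11 for the PI3K Akt mTOR pathway (adjusted p = 0.0401) and -0.18 for histones (adjusted p = 0.0413). None of these passed with an estimated correlation, each at adjusted p = 0.518 with an estimated correlation. All 5 calls also ended once the polysomal arrays were scaled to equal separation, where the median was 0.0013 for secreted and membrane proteins and -0.0124 for extracellular matrix. Quantile normalization ended those of translation factors, PI3K genes and histones. Without CD95L-T4 polysomal replicate 2 the medians were larger, at 0.11 for translation factors, 0.14 for PI3K genes and -0.30 for histones. They were then 0.12 for extracellular matrix and 0.13 for secreted and membrane proteins. Members with small p were Igfbp5 (0.38) and Scg2 (-0.47), Tnc (0.34), Fn1 (0.28) and Sparc (0.25), Eif2b1 (0.20), Eif4h (0.19) and Eif3i (0.18), Pdpk1 (0.21), and H3c4 (-0.77), H1f4 (-0.39) and H1f2 (-0.18). The histone call was also lost with a replicate block over all arrays and on leaving out any 1 of 6 arrays, and the PI3K call on leaving out any 1 of 5. Both also ended without the dimmest 50% of probe sets and with the mean of all probe sets of a gene, and the PI3K call without the dimmest 25%. The extracellular matrix call was lost without CD95L-T4 polysomal replicate 1 or control polysomal replicate 3, and the call of translation factors without CD95L-T4 polysomal replicate 1. Adjusted over the list alone, 1 histone gene and 1 Notch or Wnt gene were lower and 0 members of the other lists passed, with 0 over all probe sets. Median, mean and test differed in sign for the ER chaperone, oligodendrocyte, microglia and immediate early lists, of which 0 were called. Across the 12393 genes the effects in total and polysomal RNA correlated at a Pearson coefficient of 0.105 and a Spearman coefficient of 0.110. Without CD95L-T4 polysomal replicate 2 the Pearson coefficient was 0.0471, and it was 0.0674 without control polysomal replicate 1, 0.0685 without CD95L-T4 total replicate 1 and 0.0689 without control total replicate 4. Genes are not independent replicates, and the Pearson coefficient ranged from -0.32 to 0.48 in permuted residuals without any effect.

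The fourth question was which mRNAs of control cultures were over- or under-represented on polysomes. Most listed genes of secreted and membrane proteins and of the extracellular matrix were lower in polysomal than in total RNA. Tnc, the matrix glycoprotein tenascin C, fell from 11.87 ± 0.07 to 8.94 ± 0.09 (SD, n = 4 and 4), 7.62-fold (adjusted p = 2.03e-11), and Itgb1, the integrin beta 1 chain, fell 5.85-fold (adjusted p = 5.13e-10). With 1 probe set standing for each gene and groups that did not overlap, the largest falls were of ND5, a message made and translated inside mitochondria (9.82-fold, from 12.60 ± 0.11 to 9.31 ± 0.45), and of Xist, the noncoding nuclear RNA of the inactive X chromosome (8.85-fold, from 12.17 ± 0.15 to 9.02 ± 0.16). On the same basis the largest rise was of H1f4, a linker histone gene (9.53-fold, from 4.58 ± 0.40 to 7.83 ± 0.31, adjusted p = 1.81e-10), followed by Mt3, a metallothionein (4.74-fold). The total RNA level of H1f4 lay near the 25th percentile of probe sets and was not shown to be above background, so its fold and rank are uncertain.

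limma called 12704 of 22626 probe sets (56.2%), 6745 higher and 5959 lower in polysomal RNA, of 7022 genes. Changes of over 2-fold were more often falls, with 1439 lower and 1032 higher. With arrays shifted to equal medians 8894 were higher and 5162 lower, and the median of all probe sets was 0.15 rather than 0.06, so that the balance of rises and falls depended on the scaling. The other large falls were of Acaca, the first enzyme of fatty acid synthesis (5.47-fold), the surface protein gene Cd109 (5.32-fold), Phxr4 (5.31-fold), the Golgi glycoprotein gene Glg1 (5.22-fold), and the collagen genes Col5a2 (5.12-fold) and Col4a5 (4.91-fold). The other large rises were of Atf5, a stress-response transcription factor with upstream open reading frames (3.62-fold, from 7.62 ± 0.03 to 9.48 ± 0.11), Swsap1 (4.01-fold), Smim27 (3.92-fold), Tmem242 (3.66-fold), Ankrd24 (3.56-fold) and the little characterised 1810044D09Rik (4.11-fold), 1110032A03Rik (3.76-fold) and ccdc198 (3.71-fold). The lower level of Acaca, Phxr4 and ccdc198 lay under the 25th percentile of probe sets, which makes their folds uncertain too.

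Only 3 lists held with an estimated correlation as well as the preset one. Of 39 genes of secreted and membrane proteins, 35 fell and 1 rose, with a median of -1.31 (adjusted p = 4.6e-18; adjusted p = 0.0164 with an estimated correlation). They included the semaphorin receptor Plxnb2 (3.59-fold), the growth factor binding protein Igfbp5 (4.32-fold) and the cell adhesion molecule Ncam1 (2.87-fold). Of 30 extracellular matrix and adhesion genes, 23 fell and 0 rose, with a median of -1.40 (adjusted p = 1.35e-11; adjusted p = 0.0251 with an estimated correlation), among them the dystroglycan gene Dag1 (3.42-fold) and Itga6 (3.40-fold). Of 18 cytoplasmic aminoacyl-tRNA synthetases, which load tRNAs, 16 fell and 0 rose, with a median of -0.63 (adjusted p = 9.51e-08; adjusted p = 0.0377 with an estimated correlation), among them Aars (2.69-fold), Lars (1.98-fold) and Rars (1.91-fold). Each list was lower in 4 of 4 polysomal arrays, and the same number of members passed adjusted over the list alone.

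**Figure D2:**
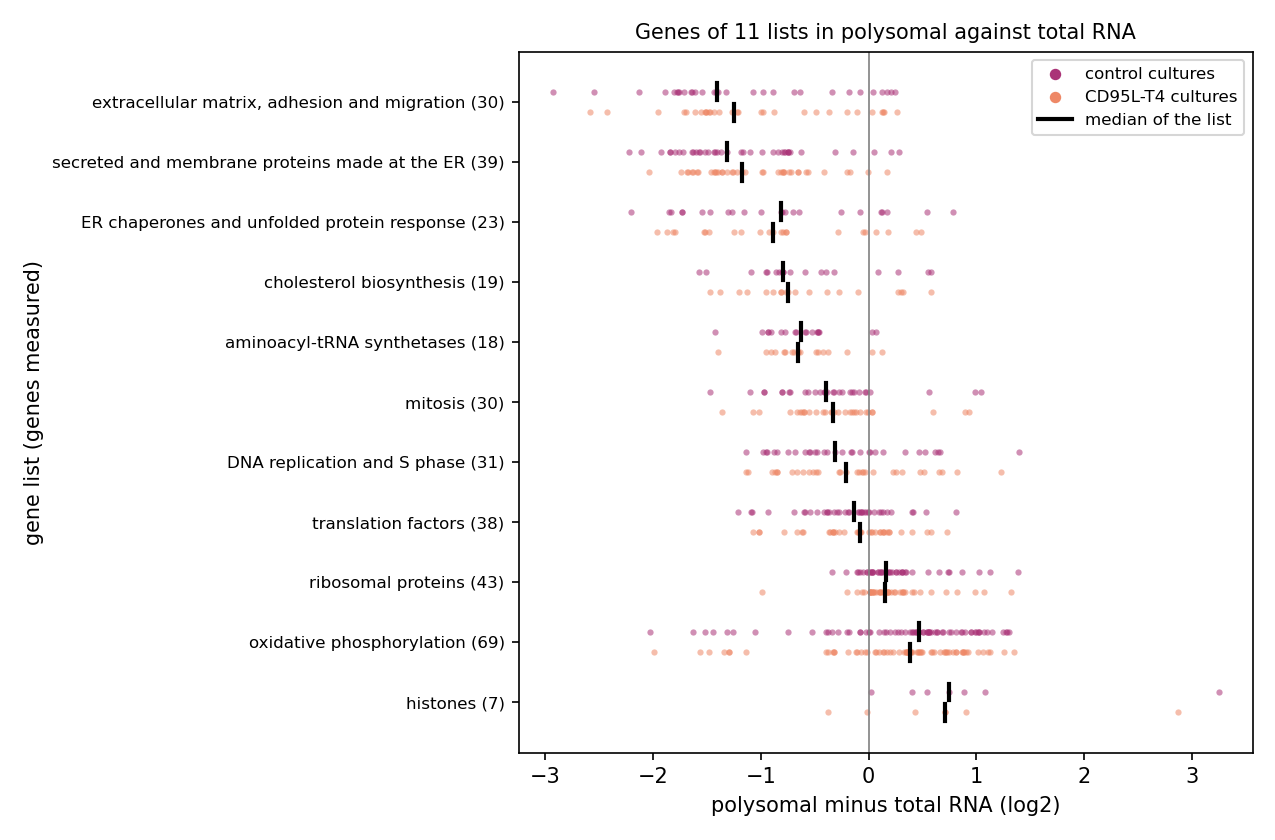
Each point is a gene of 1 of the 11 lists called in control cultures, placed at its log2 difference between polysomal and total RNA; the upper line of points of a list is from control and the lower from CD95L-T4 cultures, and black bars are medians. The lists of matrix and of secreted proteins have the lowest medians, -1.40 and -1.31 in control cultures, and the histones the highest, 0.75.

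The other 8 called lists did not hold with an estimated correlation. Of 23 ER chaperone genes 17 fell and 2 rose (median -0.81, adjusted p = 3.49e-07; adjusted p = 0.149 with an estimated correlation), with the ER chaperone Hspa5 (2.92-fold), the disulfide isomerase Pdia6 (3.55-fold) and Sel1l of ER-associated degradation (3.61-fold) lower. Of 19 cholesterol genes 15 fell and 3 rose (median -0.79, adjusted p = 1.99e-05; adjusted p = 0.0515 with an estimated correlation), with the ER enzymes Cyp51 (2.97-fold), Sqle (2.85-fold) and Ebp (2.13-fold) lower. Of 30 mitosis genes 19 fell and 3 rose (median -0.40, adjusted p = 5.93e-05; adjusted p = 0.231 with an estimated correlation), with Mki67 lower (2.78-fold) and the centromeric histone Cenpa higher (1.98-fold). Another probe set of the topoisomerase Top2a (2.14-fold lower) was higher by 0.49 in log2 and passed. Of 31 DNA replication genes 16 fell and 7 rose (median -0.31, adjusted p = 0.0108; adjusted p = 0.283 with an estimated correlation), with Rrm1 (2.20-fold) and Mcm6 (1.92-fold) lower and the transcription factor E2f1 higher (2.63-fold). Of 38 translation factors 18 fell and 4 rose (median -0.14, adjusted p = 0.00786; adjusted p = 0.298 with an estimated correlation), with Eif3a (2.31-fold), Eif4g3 (2.13-fold) and Eif3c (2.12-fold) lower.

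Among the lists that were higher, 46 of 69 oxidative phosphorylation genes rose and 14 fell (median 0.47, adjusted p = 0.00282; adjusted p = 0.348 with an estimated correlation). The 3 with the smallest p went the other way: Sdha, the flavoprotein of complex II (4.07-fold), Ndufs1, a large subunit of complex I (3.08-fold), and Atp5a1, the ATP synthase alpha subunit (2.86-fold), fell. Of 43 ribosomal protein genes 22 rose and 2 fell (median 0.16, adjusted p = 0.0232; adjusted p = 0.273 with an estimated correlation), with Rps25 (2.62-fold), Rpl37 (2.19-fold) and Fau (1.82-fold) higher. Quantile normalization over all arrays also ended that call. Of 7 histone genes 6 rose and 0 fell (median 0.75, adjusted p = 0.0132; adjusted p = 0.194 with an estimated correlation), with H2aw (by 1.08 in log2) and H1f2 (1.85-fold) higher beside H1f4. Without the dimmest 50% of probe sets the calls of histones, translation factors and DNA replication were lost. All 8 lists lay on the side of their median in 4 of 4 polysomal arrays. Adjusted over the list alone, 22 mitosis genes fell, 5 translation factors rose and 15 oxidative phosphorylation genes fell, and the other counts of these lists were as over all probe sets.

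**Figure D3:**
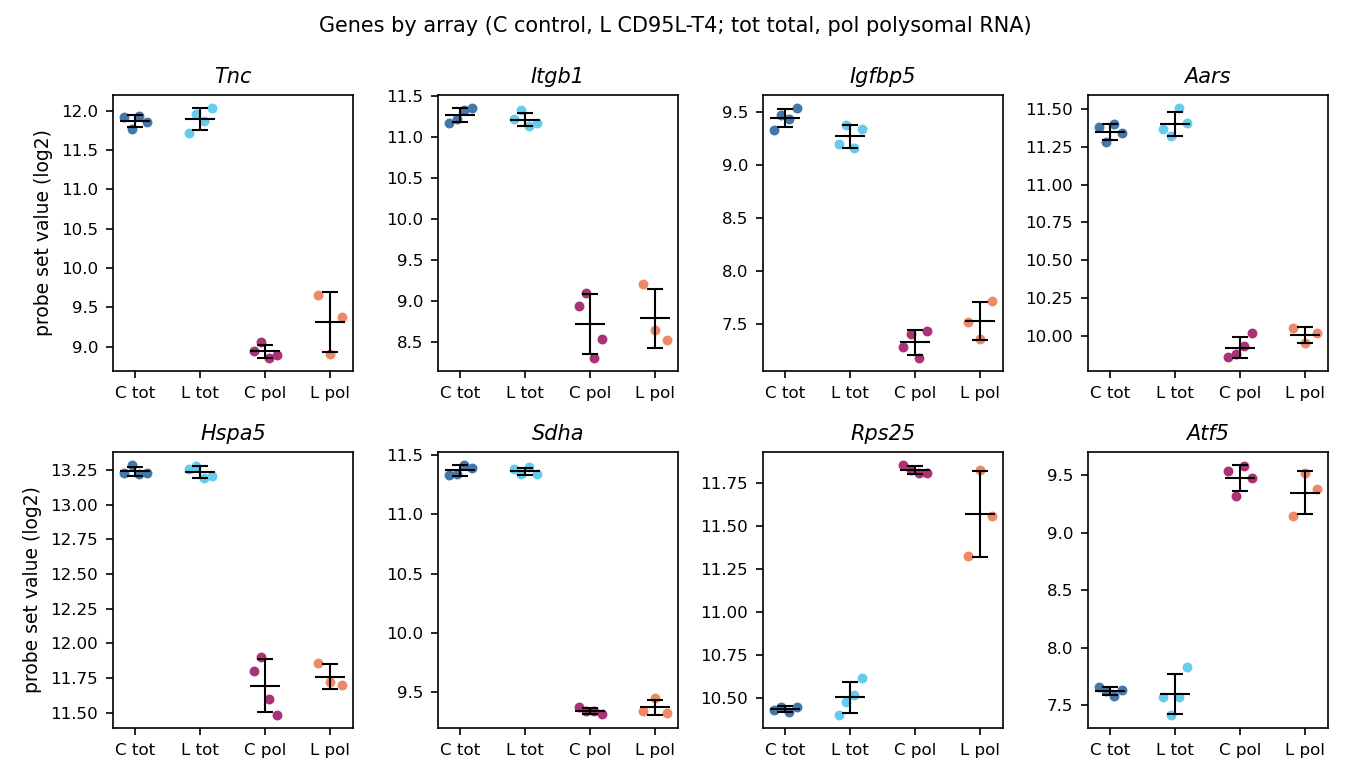
Log2 probe set values of 8 genes in every array, by group, in order of replicate number; bars are the mean and the SD (n = 4, and n = 3 for CD95L-T4 polysomal). Tnc, Itgb1, Igfbp5, Aars, Hspa5 and Sdha are lower and Rps25 and Atf5 are higher in every polysomal than in every total RNA array.

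Of the genes of CD95 signalling and cell identity, Eif4ebp1 rose 2.71-fold (adjusted p = 5.22e-10), Atf4, a stress-response transcription factor translated through upstream open reading frames, rose 1.71-fold (adjusted p = 2.36e-08), and Akt1 rose 1.42-fold (adjusted p = 0.000198). Sox2 fell 1.49-fold (adjusted p = 0.000526), and Nes fell 1.45-fold (adjusted p = 0.00233), but not with the poly-A controls as a covariate (log2 -0.26). Mtor fell 1.48-fold by its brighter probe set and was higher by 0.51 in log2 by the other, so its direction is open. Gfap was 1.34-fold higher (adjusted p = 0.0219), but this was lost without control total replicate 1 or control polysomal replicate 1. Malat1, a nuclear noncoding RNA, was 1.90-fold lower (adjusted p = 0.0371), and this was lost without control total replicate 2 (adjusted p = 0.148) or without control polysomal replicate 3 or 4. Casp8 rose 1.24-fold (adjusted p = 0.0104). Fas, Fasl, Dcx, Tubb3 and Olig2 did not pass.

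The 18 other lists were not called by camera in control cultures. Medians were 0.30 for death receptor and apoptosis genes, 0.27 for p53 targets, 0.36 for ependymal, 0.20 for endothelial, 0.18 for microglial and 0.12 for neuronal markers, and 0.26 for noncoding RNAs. They were 0.12 for the NF-kB, 0.20 for the immediate early and 0.11 for the interferon response, 0.17 for Notch and Wnt targets, 0.04 for oligodendrocyte and 0.05 for fibroblast markers. Lower medians were -0.27 for astrocyte and -0.03 for stem cell markers, -0.21 for the PI3K Akt mTOR pathway, -0.16 for glycolysis and -0.00 for the ATF4 response. Median, mean and test differed in sign for the ATF4, oligodendrocyte, fibroblast, interferon and Notch and Wnt lists. fry called 26 of the 29 lists.

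The last question was whether the same representation held after CD95L-T4. Xist (8.49-fold), ND5 (6.80-fold), Tnc (6.01-fold) and Itgb1 (5.35-fold) were again among the large falls, with Tnc at 11.90 ± 0.14 in total (SD, n = 4) and 9.31 ± 0.38 in polysomal RNA (n = 3). Acaca (6.49-fold), Phxr4 (4.49-fold), Glg1 (4.21-fold), the amyloid precursor gene App (-2.03 in log2), the ubiquitin ligase gene Nedd4 (4.04-fold) and the guidance molecule gene Ntn1 (4.02-fold) also fell. With 1 probe set standing for each gene and groups that did not overlap, H1f4 had the largest rise (7.30-fold, from 4.39 ± 0.21 to 7.26 ± 0.17), uncertain in size because its total RNA level, like the polysomal level of Acaca and Phxr4, lay under the 25th percentile of probe sets, followed by Ddit4 (4.31-fold, from 7.43 ± 0.73 to 9.53 ± 0.58) and Max (3.79-fold). The chaperone gene Cryab (3.48-fold), Ankrd24 (3.44-fold), Atf5 (3.38-fold), the splicing factor gene U2af1 (3.35-fold), Pkig (3.33-fold), Ccdc59 (3.30-fold) and Rab5c (3.30-fold) followed. Cdkn1a, the p53-induced cell cycle inhibitor, rose 2.12-fold (adjusted p = 8.5e-08), Aen 1.84-fold and Bbc3 1.69-fold, and 10 of 17 p53 targets rose and 0 fell (median 0.43, adjusted p = 0.0186; adjusted p = 0.167 with an estimated correlation), a call lost with the mean of all probe sets of a gene. Of 23 astrocyte genes 11 fell and 5 rose (median -0.23, adjusted p = 0.0419; adjusted p = 0.107 with an estimated correlation), with Sparcl1 (3.14-fold), Cd44 (2.74-fold) and Mlc1 (2.47-fold) lower, a call lost without CD95L-T4 total replicate 1 or without CD95L-T4 polysomal replicate 2 (adjusted p = 0.081) or 3, and also with array weights, the poly-A covariate, the mean of all probe sets of a gene or without the dimmest 50% of probe sets.

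limma called 11603 of 22626 probe sets (51.3%), 6044 higher and 5559 lower, of 6371 genes. With equal medians 7866 were higher and 4799 lower. Probe sets called in both cultures numbered 10286, of which 10285 had the same direction, against 3265.8 for unrelated calls. The exception, a probe set of the mitochondrial ribosomal protein gene Mrps11 named after its value was seen, stood at 0.24 and -0.33, and its interaction did not pass (adjusted p = 0.897). Across genes the effects of fraction in the 2 cultures correlated at 0.961. Of the genes of CD95 signalling and cell identity, Eif4ebp1 (1.24), Akt1 (0.65) and Atf4 (0.64) rose and Mki67 (-1.36), Nes (-0.48) and Mtor by its brighter probe set (-0.49) fell, whereas Sox2 (-0.28), Malat1 (-0.36), Gfap (0.08), Casp8 (0.10), Fas (-0.12), Fasl (0.12), Dcx (-0.02), Tubb3 (0.14) and Olig2 (-0.06) did not pass. The same 3 lists held with an estimated correlation: secreted and membrane proteins (35 of 39 lower, median -1.17, adjusted p = 2.59e-18; adjusted p = 0.0155 with an estimated correlation), extracellular matrix (23 of 30 lower and 1 higher, median -1.24, adjusted p = 1.99e-11; adjusted p = 0.0264 with an estimated correlation) and synthetases (15 of 18 lower, median -0.65, adjusted p = 1.99e-07; adjusted p = 0.0459 with an estimated correlation). ER chaperones (adjusted p = 9.98e-08; adjusted p = 0.107 with an estimated correlation), cholesterol genes (adjusted p = 5.58e-05; adjusted p = 0.0678 with an estimated correlation), mitosis (adjusted p = 0.00029; adjusted p = 0.283 with an estimated correlation) and DNA replication (adjusted p = 0.0389; adjusted p = 0.416 with an estimated correlation) were lower, the last only with CD95L-T4 total replicate 1 and CD95L-T4 polysomal replicates 2 and 3 in the fit, and not with the mean of all probe sets of a gene or without the dimmest 25% or 50% of probe sets. Oxidative phosphorylation (adjusted p = 0.0024; adjusted p = 0.416 with an estimated correlation) and ribosomal proteins (adjusted p = 0.024; adjusted p = 0.283 with an estimated correlation) were higher, the latter not with quantile normalization over all arrays. Members with the smallest p included Cd81 (2.98-fold lower) of membrane proteins, Canx (3.47-fold lower) of ER chaperones, Vars (1.93-fold lower) of synthetases, Srebf2 (1.93-fold lower) of the cholesterol pathway and Rps6 (1.76-fold higher) of ribosomal proteins. Translation factors (median -0.08, adjusted p = 0.0812) and histones (0.71, adjusted p = 0.0528) did not pass. Lists called in 1 culture alone are not shown to differ between cultures, since of the interaction lists 0 passed with an estimated correlation. Median, mean and test differed in sign for the PI3K Akt mTOR, ATF4, interferon and Notch and Wnt lists, and fry called 23 lists.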

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

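The tests of an effect shared by all CD95L-T4 cultures, of mRNA input and of RNA integrity were chosen only after the result was seen. The scaling to equal separation was also added after the data were seen. The calls without CD95L-T4 polysomal replicate 2 were themselves a pattern found in the data.

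The poly-A controls averaged 10.01 in CD95L-T4 polysomal replicate 2, against at most 9.17 in control polysomal arrays, a signal in probe sets that the gene comparisons did not use. Without that array 1386 probe sets passed for CD95L-T4 in polysomal RNA. Along the fraction axis CD95L-T4 polysomal replicates 1 and 3 stood at 0.84 and 0.86, against 0.94 to 1.03 in controls. Replicate 2, the array left out, stood at 0.998, within the range of the controls. On the second principal component replicates 1 and 3 stood at -14.06 and -21.76, replicate 2 at 14.37 and control polysomal arrays at -6.47 to 17.03. A weaker separation of polysomal from total RNA in replicates 1 and 3 is a candidate explanation. Across genes their effect of CD95L-T4 and the difference between fractions, computed from separate control polysomal arrays, correlated at -0.462 to -0.252. After scaling to equal separation 172 of the 1386 still passed, the median size falling from 0.40 to 0.33 with nearly the same standard error. Weaker separation thus stays open as the whole cause. RNA integrity or labelling of replicates 1 and 3 was not tested as a cause and stays open. The amount of mRNA in labelling is open too, with 461 still called beside the poly-A covariate in the fit to all groups. In the polysomal arrays alone the covariate lowered the count at an unadjusted p under 0.05 from 4163 to 1163, with 0 called either way. Both CD95L-T4 arrays kept had lower poly-A controls (8.31 and 8.45) than any control polysomal array (8.56 to 9.17), so the covariate cannot be told apart from CD95L-T4 there. An effect of CD95L-T4 in all or some cultures is open as well. On it the median deviation of the array left out (at most -0.015) decides nothing, since that array was singled out because its absence raised the count. Of the 15 splits of the 6 arrays left, 1 gave as many as the real 1386 (highest other 0), too few splits for a share under 0.05.

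Most listed genes of secreted and membrane proteins were lower in polysomal RNA, with a median of -1.31 for the list in control cultures. Gene span, the length of the gene on the genome, is argued against as the whole cause, since the median stayed at -1.198 once the trend with span was removed (Spearman coefficient of span and fraction effect -0.31 across genes; span known for 39 of 39 members). The scaling between arrays was tested only in part. The highest median under the other 3 scalings was -1.222, but the deposited table was already normalised between arrays. What that normalization did to the difference between fractions could not be seen. The large 3' bias taken as the sign of lost RNA integrity was not seen. The 3' minus 5' difference in polysomal RNA rose by 0.362 for beta-actin, 0.295 for Gapdh and 0.55 for Tfrc, and changed by -0.67 for Pcx. Because that sign was chosen after the result was seen, a smaller loss of integrity stays open. Transcript length, which could not be tested, stays open beside integrity and normalization. The preparation stays open too, since only polysomal RNA was extracted with phenol and chloroform and only its molecule is labelled polyA RNA. Messages bound to the ER may also be lost with membranes in preparing the lysate. The poly-A controls averaged 8.87 in control polysomal and 7.98 in control total arrays, and the list's call held with their level as a covariate. No value separates the preparation from the biological reading that these messages carried fewer ribosomes, because fraction and method coincide.

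Whether other splits of the same arrays gave as much was counted for each comparison. In total RNA 18 of 35 splits gave as many probe sets at an unadjusted p under 0.05 as the real 846 (highest other 2683), and 2 of 35 gave as many called lists as the real 4 (highest other 4), so chance is not excluded. The highest split put replicates 1 and 2 of both groups together. It was picked as the highest of the splits, and no structure of the samples behind it was tested. In polysomal RNA 7 of 35 splits gave as many probe sets as the real 2184 (highest other 5017) and 7 of 35 as many lists as the real 7 (highest other 9), so chance is not excluded. The highest split joined CD95L-T4 polysomal replicates 1 and 3 with control polysomal replicate 4, and called 1261 probe sets where the real split called 0. Whether a structure of the samples or CD95L-T4 lies behind that split, also picked as the highest, was not tested. For the interaction 54 of 100 splits gave as many probe sets as the real 992 (highest other 3818) and 16 of 100 as many lists as the real 5 (highest other 10), so chance is not excluded. Between fractions 1 of 35 splits gave as many called probe sets in control cultures, the real one with 12704 (highest other 0). In CD95L-T4 cultures it was again 1 of 35, the real one with 11603. A share of 1 in 35 is the smallest that 35 splits can give, so chance is argued against for both but not excluded. The highest other split in CD95L-T4 cultures, with 7436, set total replicates 2, 3 and 4 against the rest and so nearly repeats the real one. The number of called lists could not decide on chance here. As many as the real 11 were called in 9 of 35 splits in control cultures (highest other 14) and in 6 of 35 in CD95L-T4 cultures (highest other 14). The highest split in control cultures joined total replicates 1, 2 and 3 with polysomal replicate 4, and so kept part of the fraction difference. In CD95L-T4 cultures it joined total replicate 2 with polysomal replicates 2 and 3. In the 20 sets of permuted residuals at most 7 (control) and 6 (CD95L-T4) lists were called.

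A few lists differed in their CD95L-T4 effect between polysomal and total RNA by camera with the preset correlation, and not with an estimated one: PI3K Akt mTOR pathway (0.105), translation factors (0.066), extracellular matrix (0.092), histones (-0.176) and secreted and membrane proteins (0.090).

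Of 317 groups of 4 arrays examined, 13 held an array far from the others, where chance gives 15.8, about 1 in 20 groups. The gap to the nearest array as a share of the group's range is given for each. Ddit4 stood at 8.51 in CD95L-T4 total replicate 1 against 7.02 to 7.12 in the others (0.933). Malat1 stood at 12.03 in control total replicate 2 against 10.59 to 10.76 (0.882). The poly-A control mean of control total replicate 1 was 7.55 against 8.09 to 8.18 (0.850), and the array median of control polysomal replicate 3 was 6.83 against 6.85 in all others of its group (a share of 1). H3c4 stood at 6.04 in control total replicate 3 against 6.57 to 6.65 (0.869), and Sel1l at 6.74 in control polysomal replicate 2 against 6.36 to 6.40 (0.895). Among control total arrays Ncam1 in replicate 1 was 9.33 against 9.12 to 9.13 (0.952), Nsdhl in replicate 4 was 10.53 against 10.68 to 10.71 (0.833), and Bspry in replicate 4 was 4.92 against at most 5.01 (0.889). In control total replicate 2 Hspa5 was 13.29 against 13.22 to 13.23 (0.857), Sox2 was 11.63 against 11.71 to 11.72 (0.889), and 2310010J17Rik was 6.63 against 6.71 to 6.72 (0.889). Sparc in CD95L-T4 total replicate 2 was 9.24 against 9.12 to 9.14 (0.833).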

How the results depend on the processing

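Chosen only after the result was seen were the settings with the poly-A covariate, with polysomal arrays scaled to equal separation, and without both CD95L-T4 total 1 and CD95L-T4 polysomal 2. The called counts for CD95L-T4 stayed at 0 in total RNA in all 29 settings, with 375 to 2018 probe sets at an unadjusted p under 0.05. With 1 array left out, the count was 0 to 1386 in polysomal RNA, 0 to 2 in the interaction, and 0 to 0 in total RNA; without both arrays just named it was 1322 (681 higher, 641 lower) in polysomal RNA and 1, the probe set without a gene name, in the interaction. In the other settings polysomal and interaction counts were 0. Counts between fractions ran from 11761 to 13070 in control and from 11039 to 11578 in CD95L-T4 cultures with 1 array left out, and fell to 7216 and 6995 with the size threshold of 0.5, by its construction. The correlation of treatment effects ran from 0.0471 (without CD95L-T4 polysomal 2) to 0.145 with 1 array left out, against 0.105 with all arrays.

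List calls over the 5 contrasts numbered 38, 33 to 40 with 1 array left out, and 6 with an estimated correlation; the cause was not tested. Of the 60 named genes past the threshold in control cultures 4 lost the call in some setting, and 0 of 52 in CD95L-T4 cultures. Reversed results were the extracellular matrix list (-0.0152, adjusted p = 0.986) and the list of secreted and membrane proteins made at the ER (-0.0476, adjusted p = 0.037) in polysomal RNA after CD95L-T4, both with polysomal arrays scaled to equal separation, and the ATF4 list between fractions in control cultures with fry (-0.0038, adjusted p = 0.0157), where the median and fry's direction differ; the cause was not tested. A fixed replicate block gave 12731 (control) and 11597 (CD95L-T4) over all arrays and 12409 and 11008 within each fraction, with 0 for CD95L-T4. The block over all arrays also ended the calls of cholesterol and DNA replication in polysomal RNA and of histones in the interaction, and the block within fractions that of cholesterol. Residuals of same-number arrays correlated at -0.23 to 0.20, so a pairing by number was not shown. A pseudocount was not run, the table being in log2, and for dim genes such as Fas the signal over background limits what can be seen.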

Other observations

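All families described here were chosen after their values were seen.

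Beyond the lists fixed in advance, 60 of 74 genes of mitochondrial ribosomal proteins were higher in polysomal than in total RNA of control cultures and 5 were lower, with a median of 0.80, a 1.75-fold rise (adjusted p = 6.12e-12 over 8 families; adjusted p = 0.138 with an estimated correlation). After CD95L-T4 63 rose and 3 fell, with a median of 0.76. Host genes of small nucleolar RNAs, whose introns carry the small RNAs, rose for 5 of 6 genes, with a median of 0.85 (adjusted p = 0.0111; adjusted p = 0.173 with an estimated correlation). Of 173 zinc finger genes named Zfp, 98 rose and 20 fell, with a median of 0.35 (adjusted p = 7.17e-05; adjusted p = 0.138 with an estimated correlation). Kinesins, the motor proteins of microtubules, were lower for 15 of 24 genes and higher for 1, with a median of -0.35 (adjusted p = 0.000328; adjusted p = 0.0649 with an estimated correlation). These medians kept their sign under all 3 other scalings between arrays. A median fall as large as that of the listed secreted and membrane proteins was not seen in solute carriers, a family of membrane proteins. In control cultures 72 of 262 genes fell and 53 rose, with a median of 0.03 (camera adjusted p = 0.033 towards lower, and 0.323 with an estimated correlation). After CD95L-T4 77 fell and 34 rose, with a median of -0.04 (camera adjusted p = 0.00277 towards lower, and 0.17 with an estimated correlation). Dim solute carrier genes were not left out. Of 19 vacuolar ATPase subunits 8 fell and 7 rose in control cultures, with a median of 0.12 (camera adjusted p = 0.561).

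Genes of proteasome subunits had a median of 0.17 for CD95L-T4 against control in polysomal RNA and -0.01 in total RNA. Of the 39 genes 0 passed, and the list (adjusted p = 1.18e-07) did not pass with an estimated correlation (adjusted p = 0.426 with an estimated correlation). In control cultures 18 of them were lower and 5 higher on polysomes, with a median of -0.23 (adjusted p = 0.00611; adjusted p = 0.512 with an estimated correlation), and in CD95L-T4 cultures 11 were lower and 8 higher, with a median of -0.04 (adjusted p = 0.296).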
